A study of Arabidopsis thaliana with 21 samples.

How the data were processed

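RNA sequencing data of 21 Arabidopsis libraries were used, 12 of roots and 9 of leaf mesophyll protoplasts, 3 in each of 7 groups. Per the labels, the 3 libraries of a group are biological replicates, and groups were taken from the labels. One label field of the protoplast libraries names Ler seedlings while the genotype field names Col-0 plants, and the protoplast origin is therefore given as the genotype field states it. Plants for protoplasts were aged 4 weeks and grew with 8 h of light and 16 h of dark. Per the labels, reads came from a BGISEQ-500 instrument and were mapped to TAIR10 with HISAT and Bowtie2. Versions, read strand and counting settings are not given in the sources used here. The KIN10 transcript was not analysed in roots here, so the KIN10ox label was not checked against it.

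The authors deposited 4 tables, each holding only the genes they selected: 770 for nitrate in Ler roots, 862 for nitrate in KIN10ox roots, 1985 for NLP7 against GFP and 455 for NLP7 with KIN10 against GFP. Per the file headers, values per library are FPKM (fragments per kilobase, scaled to mapped fragments), TPM (scaled over all transcripts of a library) and expected counts (estimated fragments per gene). The deposited expected counts were not whole numbers in 5.06, 7.54, 2.52 and 3.30% of the genes of the 4 tables. The authors' tables also give a log2 fold change and a p value with an adjusted p value for their comparison. The headers name DESeq2 for these, while the study's description names NOISeq with a 2-fold change and a probability over 0.8. No gene fell under 2-fold, the highest adjusted p values were 0.245, 0.263, 0.141 and 0.309, and 3 genes of the last table had a p over 0.05. Tables of the same tissue gave the same values for their 504 and 375 shared genes. The protoplast tables hold 18 further columns of samples outside the study's sample list, which were not used. All gene identifiers were found in the reference annotation of the TAIR10 assembly, and 762, 857, 1963 and 451 genes had the same start and end there. Gene symbols that had been turned into dates (4) were replaced from the reference.

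Library sizes were recovered from the expected counts and FPKM of genes with a single annotated transcript and at least 200 counts. Mapped fragments numbered 19872293, 19870743 and 20236281 for Ler with KCl, 19704785, 19798774 and 19786171 for Ler with KNO3, 19825487, 19771096 and 19711192 for KIN10ox with KCl, and 19801385, 19730141 and 19890653 for KIN10ox with KNO3. In protoplasts they numbered 18298182, 16189842 and 17162068 with GFP, 18905160, 17430381 and 19096596 with NLP7, and 20221345, 20436537 and 16220378 with NLP7 and KIN10. Listed genes held 3.89 to 9.84% of the mapped fragments in roots and 2.04 to 8.64% in protoplasts. Pairs of libraries within a group differed by 2.97 to 72.5 times counting error (chi-square per degree of freedom), so no library was a copy of another. Floors of 3 counts and counting intervals cover counting error only.

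For the 4 comparisons that have a table, the calls reported are the authors' as deposited, since only selected genes have values. The edgeR and DESeq2 fits were run for these too, for the checks on simulated data and the alternatives, and decide no call. For these, folds are ratios of mean FPKM without a pseudocount, and their SE comes from the SD of each group (n = 3). A group at 0 was set to 3 counts over the group, and the fold is then given as a lower bound. For KIN10ox against Ler at each treatment, for the difference of their nitrate responses and for NLP7 with KIN10 against NLP7, genes at least 2-fold apart with libraries that do not overlap were counted. For the difference of the responses, overlap was judged on all KNO3 to KCl ratios of single libraries of each genotype. After the values were seen, edgeR quasi-likelihood tests were added for all of these comparisons. They used rounded expected counts, the recovered library sizes with no further scaling, and genes kept by filterByExpr, 972 of 1128 in roots and 1722 of 2065 in protoplasts. Spread was shared over all groups of a tissue, and p values were adjusted over the genes tested with the Benjamini-Hochberg method and a threshold of 0.05. Since the genes were selected for their response to nitrate or transfection, the shares of genes called hold for these genes alone. That selection used the same libraries, which can favour calls between groups. The adjustment covers the listed genes tested and not all genes. Genes with a group at 0 were left out of the ranking of genotype differences after CLE7 had topped it for this reason. An exact permutation test of 3 against 3 libraries cannot give a p below 0.10 and was not used.

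Before the data were examined, 20 gene lists with 276 genes, of which 275 were found in the reference, the comparisons, most alternative settings and a rule for named genes were fixed. The lists were nitrate transport, nitrate reduction and ammonium assimilation, oxidative pentose phosphate pathway and root ferredoxin reduction, nitrate-responsive regulators, NLP family and CPK kinases, the SnRK1 complex, SnRK1-induced starvation genes, ribosome biogenesis, cytokinin, organic acid metabolism, phosphate starvation, iron deficiency, defence, abscisic acid and dehydration, heat shock, photosynthesis, other leaf cell type markers, root cell type markers, cell division and the circadian clock. The rule named KIN10 and NLP7, the 8 largest rises and 8 largest falls of each comparison among genes past its threshold with at least 5 FPKM in 1 group and libraries that do not overlap, and up to 4 members past the threshold per list. It named 51, 51, 27, 26, 62, 37 and 61 genes for both nitrate responses, KIN10ox against Ler with KCl and with KNO3, NLP7 against GFP, NLP7 with KIN10 against GFP and NLP7 with KIN10 against NLP7. Further genes named in the text were chosen after their values were seen, as were the seed markers and the pathway tests, which used the annotation in the authors' tables.

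Overlaps of called genes are given beside the number expected for independent lists, n1 times n2 over the genes tested, with an exact (Clopper-Pearson) 95% interval for shares. The authors' adjusted p values imply that at least 22843, 22927, 21057 and 20594 genes were tested for the 4 tables. Comparisons that share libraries were also computed on simulated data (20 runs). With changes of known size put into simulated data, edgeR recovered 35 to 74% of 2-fold and 72 to 99% of 4-fold changes. The alternatives tried were calls of at least 4-fold, of at least 5 FPKM or without overlap of libraries, a DESeq2 test, no filter, the spread of the compared groups alone, replicate number as a block, each library left out, and a 2-fold minimum beside the adjusted p. Added later were TPM values and scaling, the authors' scaling and log2 fold change, a robust estimate of the spread, at least 2-fold in mean FPKM, an adjusted p under 0.05 in the authors' tables or with edgeR for the reversal, and leaving out KIN10ox libraries 1 and 3 with KCl. Replicate numbers were not treated as pairs in the main fits, though pairing is not excluded. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, DESeq2 1.42.0 and limma 3.58.1 were used.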

Results

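RNA was sequenced from Arabidopsis roots and leaf protoplasts in 21 libraries, 3 in each of 7 groups. The 12 root libraries came from seedlings of the wild type Ler and of a line with HA-tagged KIN10 under the 35S promoter (KIN10ox). Seedlings grew for 7 days with 5 mM nitrate and 2 days without nitrogen, and their roots were taken after 1 h with KCl or KNO3, each at 5 mM. The 9 protoplast libraries came from leaf mesophyll of Col-0 plants aged 4 weeks, transfected for GFP, for NLP7 fused to GFP, or for NLP7 fused to GFP together with Myc-tagged KIN10. KIN10 is a catalytic subunit of SnRK1, a kinase active at low cellular energy, and NLP7 is a transcription factor of nitrate signalling. Depth was 19704785 to 20236281 mapped fragments in the root libraries and 16189842 to 20436537 in the protoplast libraries. Values covered the 1128 root genes and 2065 protoplast genes that the authors listed as changed, so other genes were not analysed here. Levels are given as mean FPKM ± SD (n = 3) and folds as ratios of mean FPKM ± SE. For the nitrate responses and the comparisons with GFP, a gene is said to rise or fall where the authors listed it so. For the remaining comparisons these words stand for an edgeR call.

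The first comparison asked which genes 1 h of nitrate changed in wild-type roots. Nitrate raised genes that take up and reduce nitrate. NIR1 (AT2G15620), nitrite reductase, rose from 107 ± 7.41 to 1424 ± 20.5 FPKM, 13.4 ± 0.548-fold, and NIA1 (AT1G77760), a nitrate reductase, rose from 114 ± 4.61 to 936 ± 82.3 FPKM, 8.19 ± 0.457-fold. UPM1 (AT5G40850), which makes a precursor of the sirohaem cofactor of nitrite reductase, rose 10.4 ± 0.586-fold. The plastid enzyme G6PD3 (AT1G24280), which supplies reductant through the oxidative pentose phosphate pathway, rose from 30.3 ± 1.67 to 491 ± 23.7 FPKM, 16.2 ± 0.685-fold. IPT3 (AT3G63110), a cytokinin synthesis gene, rose from 1.27 ± 0.386 to 19.1 ± 1.64 FPKM, 15.1 ± 2.76-fold.

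Of the 18 nitrate transport genes 5 rose, among them the dual-affinity transporter NPF6.3 (AT1G12110), 6.88 ± 0.331-fold, and NRT2.2 (AT1G08100), 7.33 ± 0.824-fold. NRT2.1 (AT1G08090) rose 2.85 ± 0.0869-fold, and reads may be shared between it and the neighbouring NRT2.2. Of the 17 genes of nitrate reduction and ammonium assimilation 7 rose. In the oxidative pentose phosphate and root ferredoxin group 8 of 10 rose, including RFNR2 (AT1G30510), 9.86 ± 0.496-fold, and PGD3 (AT5G41670), 9.15 ± 0.254-fold. Of the 22 nitrate-responsive regulators 17 rose, including HHO1 (AT3G25790), 13.8 ± 3.87-fold, BT1 (AT5G63160), 12.4 ± 1.44-fold, LBD39 (AT4G37540), 11.1 ± 1.49-fold, and HRS1 (AT1G13300), 10.6 ± 0.631-fold. Cytokinin genes rose in 9 of 19 cases, with the hydroxylase CYP735A2 (AT1G67110) at 7.68 ± 1.38-fold and the response regulator ARR7 (AT1G19050) at 5.19 ± 0.849-fold. None of these groups held a gene that fell.

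In the NLP family and CPK kinase group 2 of 12 genes fell: NLP9 (AT3G59580) from 5.21 ± 0.240 to 0.467 ± 0.185 FPKM, 11.2 ± 2.57-fold lower, and NLP8 (AT2G43500) from 19.2 ± 1.84 to 5.94 ± 0.126 FPKM. Among 25 SnRK1-induced starvation genes TPS9 (AT1G23870) rose and DRM2 (AT2G33830) fell. The organic acid group held 2 rises of 8, the phosphoenolpyruvate carboxylase gene PPC3 (AT3G14940) and the kinase gene PPCK2 (AT3G04530). Of 14 iron deficiency genes 3 rose: NAS4 (AT1G56430) and the neighbours IMA1 and IMA2, whose reads may be shared. The phosphate starvation group of 10 held a rise of SPX4 and a fall of SPX1, and the abscisic acid group of 13 held a rise of PYL4 and a fall of HAI1. LUX rose among 12 clock genes, KAT1 fell among 14 other leaf cell type markers, and CAB2 fell among 15 photosynthesis genes with libraries that overlapped between KCl and KNO3. For CAB2 the authors' adjusted p was 0.112. No member was listed of the SnRK1 complex (0 of 7), ribosome biogenesis (0 of 15), defence (0 of 15), heat shock (0 of 9), root cell type markers (0 of 15) or cell division (0 of 6).

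Outside the lists, TDT (AT5G47560), a vacuolar dicarboxylate transporter, rose from 1.44 ± 0.145 to 25 ± 1.82 FPKM, 17.3 ± 1.24-fold, and AT5G65980 rose 22.2 ± 3.48-fold. Large falls were those of AT1G64590, from 306 ± 25.6 to 15.2 ± 3.37 FPKM, 20.2 ± 2.76-fold lower, and SUFE2 (AT1G67810), 7.73 ± 0.481-fold lower. The authors listed 770 genes, 537 higher and 233 lower with nitrate. Their adjusted p stayed under 0.05 for 680 of these, per the authors' deposited table. The authors' scaling moved the fold changes of all genes up by 0.10 on the log2 scale against scaling by mapped fragments.

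**Figure D1:**
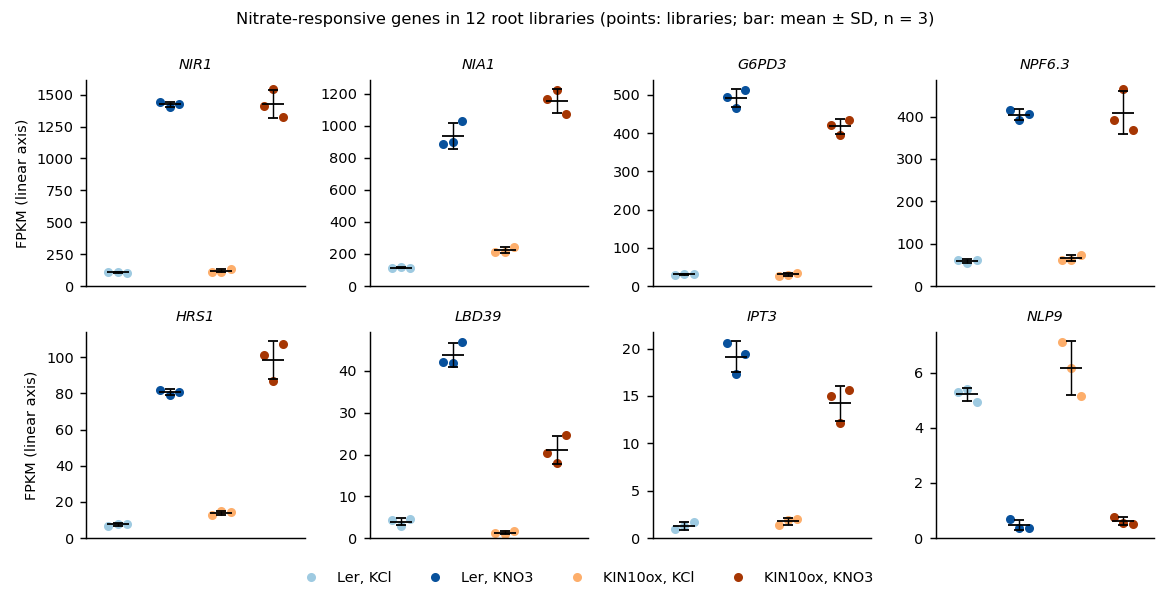
Expression (FPKM, vertical axis from 0) of 8 nitrate-response genes in Ler and KIN10ox roots after 1 h with KCl or KNO3; bars are means, error bars SD, and points single libraries (n = 3 per group). NIR1, NIA1, G6PD3, NPF6.3, HRS1, LBD39 and IPT3 were higher with KNO3 in both genotypes, and NLP9 was lower.

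The same comparison in KIN10ox roots asked whether extra KIN10 alters the nitrate response. The uptake and assimilation genes rose there too: NIR1 from 118 ± 11.8 to 1427 ± 110.4 FPKM, 12.1 ± 0.879-fold, G6PD3 13.7 ± 1.07-fold, NPF6.3 6.24 ± 0.588-fold and NRT2.2 7.25 ± 1.29-fold. NIA1 rose from 224 ± 18.6 to 1155 ± 73.7 FPKM, 5.15 ± 0.311-fold, and IPT3 from 1.75 ± 0.330 to 14.2 ± 1.87 FPKM, 8.13 ± 1.08-fold. LBD39, a repressor of nitrogen-responsive genes, rose 16.7 ± 2.89-fold, BT1 14.9 ± 1.21-fold, and NLP9 was 9.92 ± 1.58-fold lower. By group, rises numbered 4 in transport, 6 in reduction and assimilation, 8 in the pentose phosphate group, 16 among regulators, 8 among cytokinin genes and 3 among iron genes. Falls in the regulators and assimilation genes numbered 0, while ARR15 fell among cytokinin genes, and the NLP group again held falls of NLP8 and NLP9. TPS9 rose and SEN1 and BCAT2 fell among starvation genes, and PYL4 rose and RAB18 fell in the abscisic acid group. PPC3 rose in the organic acid group, and SPX4 rose and SPX1 fell in the phosphate group. In the authors' values the adjusted p was over the threshold for ARR15 (0.160) and BCAT2 (0.215).

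In KIN10ox 11 of the 15 photosynthesis genes fell with nitrate, against 1 listed in Ler. The leaf markers KAT1 and TGG1 fell too. KAT1 was also listed as lower in Ler, with an authors' log2 fold change of -2.52 there and -1.88 in KIN10ox. In the authors' KIN10ox values the adjusted p was over the threshold for TGG1 (0.112) and for the photosynthesis genes LHB1B1 (0.0994) and CA1 (0.104). RBCS3B (AT5G38410), a Rubisco small subunit gene, went from 23.4 ± 17.7 to 0.440 ± 0.151 FPKM, and CAB3 (AT1G29910), a light-harvesting protein gene, from 27.9 ± 25 to 1.42 ± 0.384 FPKM. Reads may be shared among RBCS1B, RBCS2B and RBCS3B and among CAB1, CAB2 and CAB3, which are tandem copies. The falls followed high and unequal levels with KCl: summed over the 11 genes, the KIN10ox libraries held 269, 110.3 and 499 FPKM with KCl and 46.5, 60.0 and 49.6 FPKM with KNO3. The Ler libraries held 221, 96.1 and 109 FPKM with KCl and 105, 102 and 97.3 FPKM with KNO3. ICL (AT3G21720), isocitrate lyase of the glyoxylate cycle in oil-storing seedlings, went from 29.2 ± 27.0 to 1.27 ± 0.155 FPKM. Transcripts of 9 listed seed markers, a set chosen after the values were seen, summed to 76.8 FPKM in KIN10ox library 3 with KCl, against 7.22 and 8.66 FPKM in the other libraries of that group.

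**Figure D2:**
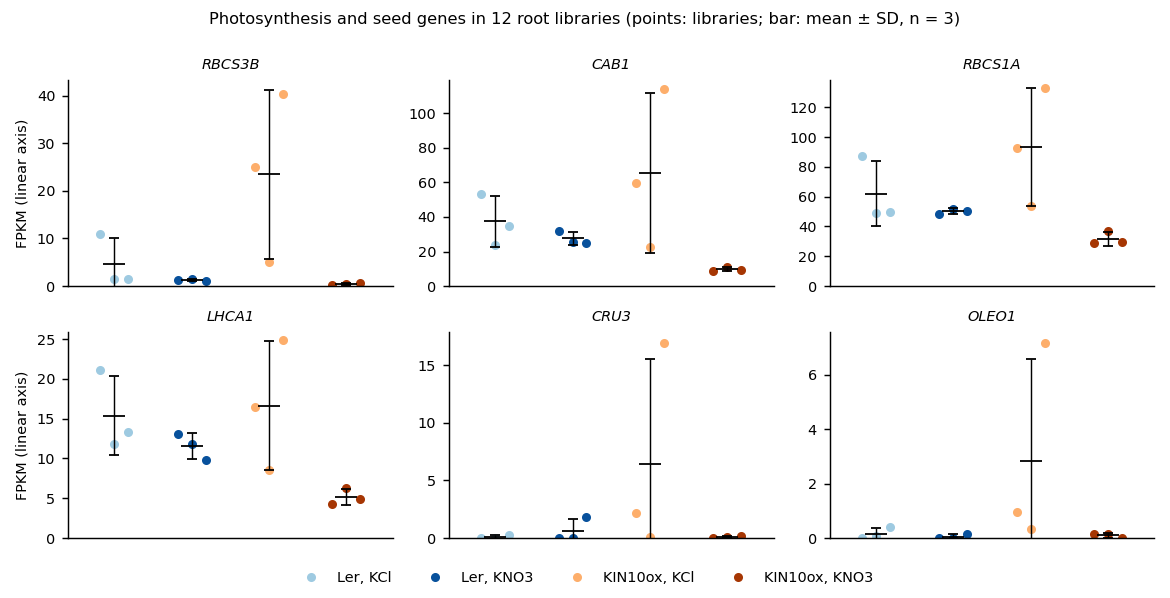
Expression (FPKM, vertical axis from 0) of 4 photosynthesis genes and of the seed genes CRU3 and OLEO1 in the 4 root groups; bars are means, error bars SD (drawn no lower than 0), and points single libraries (n = 3 per group). KIN10ox library 3 with KCl held the highest value of the group in each panel.

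The authors listed 862 genes in KIN10ox, 440 higher and 422 lower, and 664 (392 higher, 272 lower) kept an adjusted p under 0.05 in the authors' deposited table. Both genotypes shared 366 rises, against 10.3 expected for independent lists among at least 22843 tested genes, and 136 falls, against 4.30. Of the 504 genes listed in both genotypes, 502 had the same direction, 99.6% (exact 95% interval 98.6 to 99.95%). The exceptions were CYP708A3, at or below 0.38 FPKM in every library, and LpxC3, at 0 in 9 of the 12 libraries. The Ler table alone held 170 rises and 96 falls, and the KIN10ox table alone 73 rises and 285 falls. Among the 285 falls, 13 of 14 genes annotated to antenna proteins and 16 of 19 annotated to photosynthesis were found (1-sided Fisher's exact tests over 29 pathways and 236 annotated listed genes, Benjamini-Hochberg adjusted p = 9.99e-05 for each, a test chosen after the falls were seen), with 12 of 18 annotated to carbon fixation (adjusted p = 0.0461). Such tests passed no pathway for the rises in Ler and in both genotypes (lowest adjusted p = 0.335 and 0.179). Over 57 pathways and 447 annotated protoplast genes, none passed for the rises with NLP7 and with NLP7 and KIN10 (0.977 and 0.146). For NLP7 this decides nothing, since 412 of the 447 genes rose. There, 31 of 31 ribosome biogenesis genes gave an unadjusted p of only 0.0728 (1-sided Fisher's exact test). In mean FPKM, 759 of the 862 genes were at least 2-fold changed with all libraries (337 higher, 422 lower). Without KIN10ox libraries 1 and 3 with KCl these numbered 658 (311 higher, 347 lower), with 214 of the 285 falls. The authors' scaling moved the KIN10ox fold changes up by 0.20 on the log2 scale.

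The difference between both responses was then examined gene by gene. The fold rises of several assimilation and cytokinin genes were smaller in KIN10ox: NIA1 rose 8.19 ± 0.457-fold in Ler (from 114 ± 4.61 to 936 ± 82.3 FPKM) and 5.15 ± 0.311-fold in KIN10ox (from 224 ± 18.6 to 1155 ± 73.7 FPKM, thus higher at both treatments), IPT3 15.1 ± 2.76-fold and 8.13 ± 1.08-fold, and CYP735A2 7.68 ± 1.38-fold and 3.62 ± 0.778-fold. With edgeR, adjusted over the list alone, 3 of 7 assimilation genes had a lower log2 response in KIN10ox (NIA1, log2 difference -0.67 ± 0.13; NIA2, -0.31 ± 0.10; ASN2, -0.37 ± 0.13). The same held for 1 of 8 pentose phosphate genes (RFNR1, -0.39 ± 0.12), 3 of 9 cytokinin genes (IPT3, -0.90 ± 0.29; CYP735A2, -1.05 ± 0.36; CYP735A1, -0.80 ± 0.28) and 6 of 10 photosynthesis genes, among them CAB1 (-2.30 ± 0.63) and RBCS1A (-1.26 ± 0.41). In the other lists this count was 0 (0 or 1 without 1 library). A lower value is a smaller rise or a deeper fall, and can come from a higher level with KCl. With KCl, edgeR called NIA1, NIA2, ASN2, CYP735A1 and CYP735A2 higher in KIN10ox than in Ler. With KNO3 it called NIA1 higher, RFNR1 lower and no cytokinin gene, and IPT3 was called at neither treatment. Among the response differences adjusted over the list alone, only that of NIA1 stayed called without each of the 12 libraries in turn. The call of NIA2 was lost without KIN10ox library 3 or Ler library 1 or 2 with KCl or Ler library 2 with KNO3, and that of ASN2 without any but Ler library 3 with KCl, Ler library 3 with KNO3 or a KIN10ox library with KNO3. That of RFNR1 was lost without any but KIN10ox library 1 with KCl or 2 with KNO3, and that of IPT3 without any but KIN10ox library 1 with KCl, KIN10ox library 3 with KNO3 or Ler library 3 with KCl. Those of both CYP735A genes were kept only without KIN10ox library 3 with KNO3 (6 cytokinin genes) or Ler library 3 with KCl (4). All 6 photosynthesis calls were lost without KIN10ox library 3 or Ler library 2 or 3 with KCl, or KIN10ox library 1 or 3 or Ler library 2 with KNO3, and that of LHCA1 also without Ler library 1 with KNO3. CAB1 stood at 59.8, 22.4 and 114 FPKM in the KIN10ox libraries with KCl, and its difference was -1.63 without library 3 and -0.75 without libraries 1 and 3 (RBCS1A, -0.91 and -0.46). NIR1 (-0.15 ± 0.13), NPF6.3 (-0.14 ± 0.15) and G6PD3 (-0.24 ± 0.14) did not pass.

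LTP4, a lipid transfer protein gene, stayed at 7.66 ± 3.04 and 8.62 ± 3.04 FPKM in Ler and went from 4.21 ± 4.35 to 0.487 ± 0.211 FPKM in KIN10ox. The fold changes differed at least 2-fold between genotypes for 245 listed genes, 214 with the lower value in KIN10ox. Of these, 58 had KNO3 to KCl ratios of single libraries that did not overlap between genotypes. Chance gives non-overlap of 3 against 3 libraries in 10% of genes not chosen by fold. That share is no measure for such ratios or for these genes. Over all 972 genes tested, edgeR called 0 differences after Benjamini-Hochberg adjustment (lowest adjusted p = 0.0512, NIA1), with 187 genes at an unadjusted p under 0.05, 163 of them with the lower value in KIN10ox, and 120 without KIN10ox libraries 1 and 3 with KCl. DESeq2 called 41, 38 of them lower. The edgeR count was 19 without KIN10ox library 2 with KCl, 15 without Ler library 1 with KCl and 2 without KIN10ox library 3 with KNO3, and 0 in the other fits without 1 library. In simulated data, edgeR recovered 35% of 2-fold and 72% of 4-fold differences.

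Levels of KIN10ox and Ler roots were also compared at each treatment, to find genes that differ with the line itself. Without nitrate, NIA1 rose to 224 ± 18.6 FPKM in KIN10ox against 114 ± 4.61 in Ler (log2 difference 0.97 ± 0.09, adjusted p = 5.31e-05). CYP735A2, which makes trans-zeatin, was also higher (1.24 ± 0.27, adjusted p = 0.0106), as were HRS1 (0.89 ± 0.12) and ATL8 (AT1G76410), a RING finger gene, from 1.83 ± 0.211 to 8.45 ± 2.7 FPKM (2.2 ± 0.26, adjusted p = 3.05e-04). LBD39 was lower (-1.65 ± 0.22, adjusted p = 6.06e-04), as were LBD38 (-0.57 ± 0.13) and BT1 (-0.59 ± 0.15). The largest fall among the genes called at 5 FPKM or more was that of CYP76G1 (AT3G52970), a cytochrome P450 gene, from 8.62 ± 0.448 to 0.770 ± 0.332 FPKM (-3.47 ± 0.27, adjusted p = 1.66e-05), and the cell wall gene EXT13 (AT5G35190) went from 481 ± 119 to 181 ± 45.1 FPKM. Libraries of every gene named here did not overlap between genotypes, so each direction held in 3 of 3 libraries.

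At KCl edgeR called 134 of 972 genes, 75 higher and 59 lower in KIN10ox (Benjamini-Hochberg), and 120 were at least 2-fold apart and had libraries that did not overlap. Chance gives non-overlap alone in 10% of genes, which is no measure for both criteria together. Genes were listed through responses in these same KCl libraries, 285 of them only as falls in KIN10ox. Levels that were high by chance in KIN10ox with KCl can therefore favour calls of higher genes. The edgeR calls included 3 assimilation genes that rose (NIA1, NIA2, ASN2), 1 regulator that rose and 3 that fell, 2 cytokinin genes that rose, and falls of NAS4 and KAT1. Adjusted over the list alone, these groups gave the same counts with 1 more leaf marker that rose, and 2 photosynthesis genes and 2 abscisic acid genes rose and 1 abscisic acid gene fell. On leaving out 1 library, the photosynthesis genes numbered 10 without KIN10ox library 2 or Ler library 1 and 0 otherwise, the abscisic acid genes 0 to 2, and the leaf marker was lost without KIN10ox library 1 or 3 or Ler library 2 or 3. The other lists gave 0 either way. Summed photosynthesis transcripts stood at 110.3 to 499 FPKM in these KIN10ox libraries and at 96.1 to 221 FPKM in Ler. The calls of LBD38 and BT1 were lost without KIN10ox library 1, KIN10ox library 2 or Ler library 3, and that of ASN2 without any of the KIN10ox libraries or Ler libraries 1 or 2. That of CYP735A1 was lost without KIN10ox library 2 or 3 or Ler library 1 or 2, that of NAS4 without KIN10ox library 1 or Ler library 1 or 3, and that of KAT1 without any but KIN10ox library 1. The count fell to 74 without Ler library 2, to 88 without KIN10ox library 1, and to 44 without KIN10ox libraries 1 and 3, and the falls numbered 35 without Ler library 1.

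With nitrate, ATL8 was again higher in KIN10ox, from 3.87 ± 0.528 to 13.1 ± 2.4 FPKM (1.75 ± 0.24, adjusted p = 0.00125), and so was SWEET12 (AT5G23660), a sucrose transporter gene, from 2.77 ± 0.297 to 5.40 ± 0.651 FPKM (0.95 ± 0.17, adjusted p = 0.00446). LTP4 was lower, from 8.62 ± 3.04 to 0.487 ± 0.211 FPKM (-4.13 ± 0.73, adjusted p = 0.00386), as were the metallothionein gene MT2A (AT3G09390) (-1.74 ± 0.26) and the signalling peptide gene CLE7 (AT2G31082), from 5.01 ± 1.07 to 0.280 ± 0.121 FPKM (-4.05 ± 0.57, adjusted p = 0.00170). LBD39 (-1.06 ± 0.18, adjusted p = 0.00306) stayed lower, and NRT2.6 (AT3G45060) went from 1.59 ± 0.632 to 0.153 ± 0.0577 FPKM. NIA1 was still slightly higher (0.30 ± 0.09, adjusted p = 0.0471), RFNR1 (-0.41 ± 0.08) and RFNR2 (-0.35 ± 0.10) were lower, and the starvation genes DRM2 (0.60 ± 0.17) and TPS9 (0.52 ± 0.13) were higher. Each of these genes was higher or lower in 3 of 3 libraries. Photosynthesis gene LHCA1 was lower (-1.16 ± 0.34), with the summed photosynthesis signal at 46.5 to 60.0 FPKM in KIN10ox and 97.3 to 105 FPKM in Ler.

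Here edgeR called 113 genes, 26 higher and 87 lower in KIN10ox (Benjamini-Hochberg), and 103 were at least 2-fold apart without overlap (chance gives non-overlap alone in 10% of genes). The edgeR calls included NRT2.6, RFNR1, RFNR2, LBD38, LBD39, NAS4 and LHCA1, which fell, and NIA1, DRM2 and TPS9, which rose. Adjusted over the list alone, 1 regulator, 1 starvation gene, 1 organic acid gene, 1 photosynthesis gene and 1 clock gene more fell, all 5 calls being lost without Ler library 1, and the other lists gave 0. At both treatments 11 genes were higher in KIN10ox, against 2.01 expected for independent calls, and 33 were lower, against 5.28. The calls of DRM2, LHCA1 and NAS4 were lost without any 1 of the 6 libraries, that of LBD38 without Ler library 3, those of RFNR2 and TPS9 without any but KIN10ox library 3, and that of NIA1 without KIN10ox libraries 1 or 2 or Ler libraries 1 or 2. The count fell to 74, 69, 52, 60 and 61 without KIN10ox library 1, KIN10ox library 2 and Ler libraries 1, 2 and 3.

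In protoplasts the transfected genes were read first. NLP7 (chromosome 4, 12479528 to 12484049) stood at 49.9 ± 5.77 FPKM with GFP, 1916 ± 364 FPKM with NLP7, and 303 ± 105 FPKM with NLP7 and KIN10. KIN10 (AT3G01090) stood at 32.4 ± 0.763, 27.9 ± 1.97 and 413 ± 130 FPKM (SD, n = 3 each). The libraries given KIN10 thus carried less NLP7 transcript, 12.3, 8.67 and 19.7% of the added level in libraries 1, 2 and 3.

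NLP7 against GFP asked which genes NLP7 changes in leaf cells. NLP7 raised nitrate assimilation genes: NIR1 from 199 ± 15.8 to 846 ± 63.1 FPKM, 4.26 ± 0.268-fold, NIA1 3.93 ± 0.435-fold and the asparagine synthetase gene ASN2 from 1.06 ± 0.341 to 110.1 ± 6.14 FPKM, 104 ± 19.7-fold. G6PD3 rose from 2.06 ± 0.112 to 80.5 ± 8.03 FPKM, 39.2 ± 2.57-fold. The regulators HHO1, from 0.243 ± 0.0473 to 173 ± 12.7 FPKM, 711 ± 85.2-fold, and HRS1, 139 ± 52.8-fold, rose as well. Ribosome biogenesis genes rose, with the pseudouridine synthase gene CBF5 (AT3G57150) at 4.28 ± 0.355-fold and NOP58-2 (AT3G05060) at 4.26 ± 0.317-fold. PR2 (AT3G57260), a glucanase gene of defence, rose 30.8 ± 2.46-fold.

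By group, rises were 3 of 18 in transport, 4 of 17 in assimilation, 7 of 10 in the pentose phosphate group, 10 of 22 among regulators, 2 of 12 in the NLP group (NLP7 and NLP3), 9 of 15 in ribosome biogenesis, 5 of 19 among cytokinin genes and 3 of 8 among organic acid genes. Further rises were those of DIN6 (AT3G47340) among starvation genes (2.2 ± 0.158-fold), IPS1 in the phosphate group, 2 iron genes beside a fall of IMA3, PR2 in defence, 3 abscisic acid genes and PRR9 in the clock group (3.01 ± 0.727-fold). Photosynthesis genes rose in 4 of 15 cases, with LHCB2.1 (AT2G05100) at 4.63 ± 0.354-fold, and among markers of other cell types XCP1, PHO1 (AT3G23430) (13.1 ± 1.39-fold) and SCR (AT3G54220) (7.24 ± 0.954-fold) rose. No member of the SnRK1 complex, heat shock or cell division groups was listed as changed. In the authors' values the adjusted p was over 0.05 for the transport gene NPF7.3 (0.135), IPS1 (0.0802), the iron gene NAS4 (0.0935) and XCP1 (0.0712).

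Some genes went from near 0 to high levels: QWRF7 (AT4G25190) from 0.0133 ± 0.0231 to 1678 ± 210.1 FPKM, and ANNAT8 (AT5G12380) from 0 to 253 ± 26.2 FPKM, at least 3204-fold with a floor of 3 counts over the group. Falls were few and smaller, such as ORS1 (AT2G41230), from 16.2 ± 0.585 to 4.64 ± 0.866 FPKM, 3.49 ± 0.383-fold lower, and the auxin-conjugating gene GH3.3 (AT2G23170), 2.95 ± 0.556-fold lower. The authors listed 1985 genes, 1846 higher and 139 lower, and 1763 of these (1672 higher, 91 lower) kept an adjusted p under 0.05 in the authors' deposited table.

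NLP7 with KIN10 was also set against GFP. Part of the NLP7 response was left: HHO1 was 130.2 ± 37.5-fold higher than with GFP, HRS1 39.0 ± 15.6-fold, ASN2 22.7 ± 6.72-fold, RFNR2 5.24 ± 1.66-fold and G6PD3 4.67 ± 1.05-fold. PRR9 (AT2G46790), a clock gene, rose 10.2 ± 2.24-fold, the small heat shock protein gene HSP17.4 (AT3G46230) 2.54 ± 0.333-fold and RBCS2B (AT5G38420) 7.87 ± 2.26-fold. By group there were 1 rise in assimilation, 2 in the pentose phosphate group, 5 among regulators, 2 among NLP genes, 1 in the SnRK1 complex (KIN10 itself), 2 each among cytokinin, abscisic acid and heat shock genes, and 1 each among photosynthesis, root marker and clock genes. IMA3 and the defence gene PR5 fell, and in transport, ribosome biogenesis and the other groups 0 genes were listed. Of these, PR5 (0.298), both abscisic acid genes (RD29A, 0.114, and RD29B, 0.201) and NLP3 (0.214) had an adjusted p over 0.05 in the authors' values. The authors listed 455 genes, 393 higher and 62 lower, and 310 (283 higher, 27 lower) kept an adjusted p under 0.05 in the authors' deposited table. With NLP7 alone 343 of the rises and 28 of the falls were also listed, against 35.2 and 0.418 expected for independent lists. Both comparisons share the GFP libraries. Data simulated without any effect over the 2065 listed genes gave 5.85 genes called in both (edgeR, unadjusted p under 0.05 and at least 2-fold). The counts above come from the authors' calls among at least 20594 tested genes, so the simulated value is not on their scale.

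NLP7 with KIN10 against NLP7 alone asked what KIN10 changes in cells that receive NLP7. No protoplast group used here received KIN10 without NLP7, so effects of KIN10 by itself cannot be told from effects on the NLP7 response. Genes that NLP7 raised were lower with KIN10: NIR1 went from 846 ± 63.1 to 348 ± 33.0 FPKM (log2 change -1.28 ± 0.12, adjusted p = 1.27e-07), G6PD3 from 80.5 ± 8.03 to 9.61 ± 3.72 FPKM (-3.07 ± 0.22, adjusted p = 1.93e-08), ASN2 (-2.2 ± 0.23), HHO1 (-2.45 ± 0.24), CBF5 (-2.16 ± 0.17) and PR2 (-4.21 ± 0.22). A few genes were higher with KIN10, among them HSP17.4, from 33.0 ± 5.38 to 85.0 ± 17.44 FPKM (1.35 ± 0.19, adjusted p = 7.57e-06), BGLU28 (AT2G44460), a beta-glucosidase gene, from 9.87 ± 2.04 to 28.3 ± 6.78 FPKM (1.49 ± 0.20, adjusted p = 4.90e-06), HSP70-4 (AT3G12580) (0.81 ± 0.13) and PRR9 (1.76 ± 0.24). These genes changed in 3 of 3 libraries, without overlap. RBCS2B (0.70 ± 0.24, adjusted p = 0.0142) overlapped between groups and lost its call without NLP7 library 2 or NLP7 with KIN10 library 3.

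With edgeR every tested member fell in the assimilation (4), pentose phosphate (7), regulator (10), ribosome biogenesis (9), cytokinin (5), organic acid (3) and abscisic acid (3) groups. The same was so for 2 transport genes, 2 NLP genes, 2 root markers and the starvation gene DIN6. Of all tested genes that NLP7 raised, 1481 of 1552 fell as well, so the falls do not set these groups apart. In defence 1 of 2 fell, and in photosynthesis 3 of 4 fell and RBCS2B rose. KIN10, 2 heat shock genes and PRR9 rose, and 0 of 1 tested iron gene passed. Adjusted over the list alone, these counts were the same. ATL5 (AT3G62690) fell from 14.4 ± 3.56 to 0.183 ± 0.0950 FPKM (-6.31 ± 0.36, adjusted p = 2.51e-09). GL2 (AT1G79840), a regulator of epidermal cell fate, was at least 70.5-fold lower, with 0 counts in the 3 libraries with KIN10.

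Here edgeR called 1554 of 1722 genes, 66 higher and 1488 lower with KIN10 (Benjamini-Hochberg), and 1500 were at least 2-fold apart without overlap (chance gives non-overlap alone in 10% of genes). Of the 1846 genes that NLP7 raised, 1469 (79.6%) were lower with KIN10 by that measure, and of the 139 that it lowered, 12 (8.63%) were higher. With edgeR, 1481 of 1552 tested raised genes were lower with KIN10, and 46 of 115 tested lowered genes were higher and 0 lower. The median log2 change in mean FPKM over the 139 was 0.46. In 747 genes that reached at least 5 FPKM with NLP7, the median share of the NLP7-induced rise that was left with KIN10 was 11.8% (interquartile range 5.69 to 18.4%). Both comparisons share the NLP7 libraries, and data simulated without a KIN10 effect gave 0.2 of 1715 raised genes called lower. That simulation took the observed NLP7 means of the listed genes as true. It did not repeat the authors' choice among all genes, so it cannot show what that choice adds. Of the NLP7 transcript added by transfection, 13.6% was left with KIN10.

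**Figure D3:**
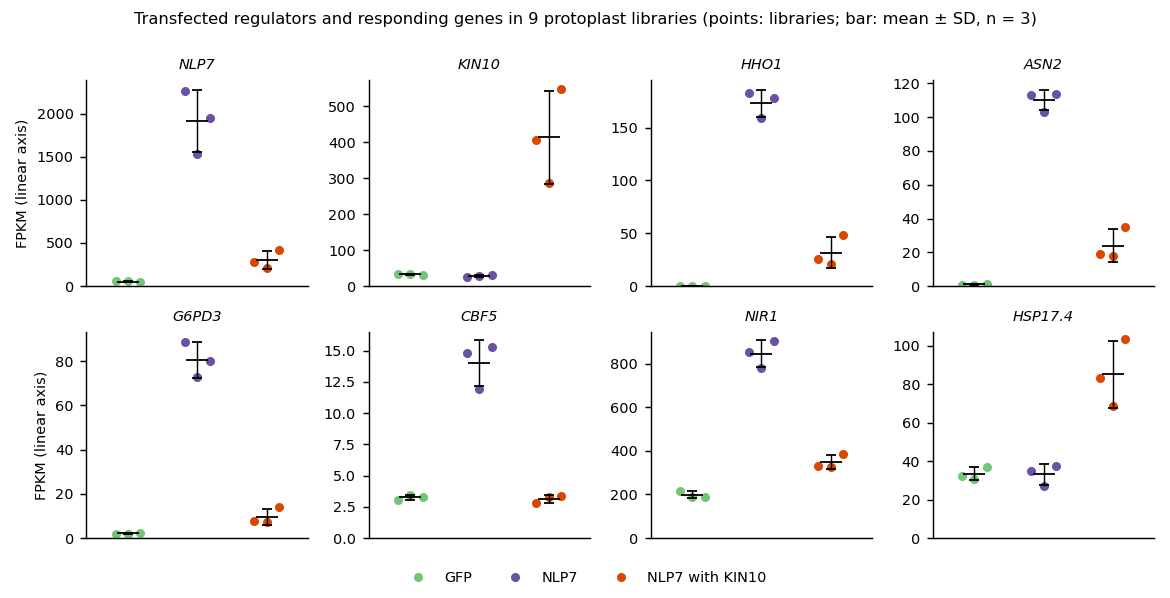
Expression (FPKM, vertical axis from 0) of NLP7, KIN10 and 6 responding genes in protoplasts given GFP, NLP7, or NLP7 with KIN10; bars are means, error bars SD, and points single libraries (n = 3 per group). HHO1, ASN2, G6PD3, CBF5 and NIR1 were lower with KIN10 than with NLP7 alone, as was NLP7, and HSP17.4 was higher.

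**Figure D4:**
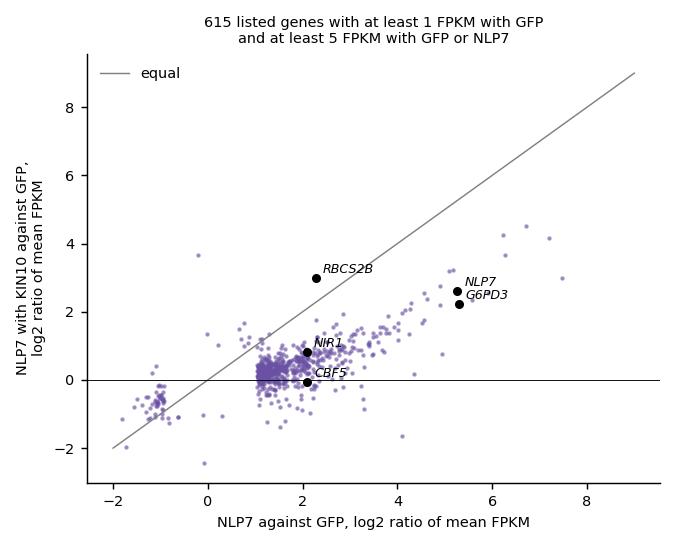
Log2 change over GFP with NLP7 (horizontal axis) and with NLP7 and KIN10 (vertical axis) for 615 listed genes with at least 1 FPKM with GFP and at least 5 FPKM with GFP or NLP7; each point is a gene and the line marks equality. Of 560 genes above 0 with NLP7, 549 lay below the line, and RBCS2B lay above it.

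Root and protoplast tables were compared to see which nitrate-regulated genes NLP7 also changed in leaf cells. G6PD3 rose 16.2 ± 0.685-fold with nitrate in Ler roots and 39.2 ± 2.57-fold with NLP7 in protoplasts, HRS1 10.6 ± 0.631-fold and 139 ± 52.8-fold, NIR1 13.4 ± 0.548-fold and 4.26 ± 0.268-fold, and AT5G65980 22.2-fold and 147-fold. Both tables shared 179 rises, against 47.1 expected for independent lists, and 5 falls, against 1.54. Of 195 genes listed in roots and in protoplasts, 184 had the same direction, 94.4% (exact 95% interval 90.13 to 97.15%). Rises made up 1846 of the 1985 NLP7 genes and 537 of the 770 Ler genes. Unrelated directions would thus also give a high share, and the interval decides nothing. Falls in roots with rises under NLP7 numbered 7, against 20.4 expected, and the reverse 4, against 3.54. NLP7 raised 33.3% of the genes that nitrate raised and 3.00% of those that it lowered (2-sided Fisher's exact test, odds ratio 16.1, p = 4.13e-24). For KIN10ox roots the shared rises were 152, against 38.6 expected, and 37 genes that fell in roots rose with NLP7, against 37.0, which left 79.2% with the same direction (72.8 to 84.6%). The limit given for the Ler share holds for this share too.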

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

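The edgeR tests themselves were added after the values were seen, and so were the settings with TPM, the authors' scaling or fold change, a robust spread, at least 2-fold in mean FPKM, an adjusted p under 0.05 in the authors' tables or with edgeR for the reversal, and without KIN10ox libraries 1 and 3 with KCl. The remaining settings were planned, for tests on tables of all genes where they apply to edgeR. Directions of the named genes held: of 2405 recomputed values for 315 named genes and comparisons, 2372 stayed within the spread between replicates, 33 moved and 0 reversed. Of the 33, 31 moved with the authors' log2 fold change and 2 on leaving out 1 library, which were AT5G10210 in Ler without library 3 with KCl (log2 8.29) and CAB2 in Ler without library 1 with KCl (log2 -0.73). Counts fell where the criterion was stricter by construction. With at least 4-fold, the counts were 199 for nitrate in Ler, 297 for nitrate in KIN10ox, 1057 for NLP7, 269 for NLP7 with KIN10 against GFP, 45 and 28 for KIN10ox against Ler with KCl and KNO3, 767 for NLP7 with KIN10 against NLP7, 104 for the difference of the responses, 122 for genes shared by both genotypes, 56 for genes shared by roots and NLP7, and 757 for the reversal. With at least 5 FPKM in 1 group they were, in the same order, 485, 445, 795, 110, 31, 24, 622, 50, 334, 105 and 618. Of the 245 response differences 58 had KNO3 to KCl ratios of single libraries that did not overlap between genotypes. With edgeR, a 2-fold minimum gave 67 genes with KCl and 54 with KNO3. The 0 edgeR differences of the response became 3 with a robust spread, 41 with DESeq2, 1 without KIN10ox libraries 1 and 3 with KCl, and 0 to 19 on leaving out 1 library (19 without KIN10ox library 2 with KCl, 15 without Ler library 1 with KCl, 2 without KIN10ox library 3 with KNO3), and the cause was not tested. Genes at an unadjusted p under 0.05 for this difference went from 187 to 120 without KIN10ox libraries 1 and 3 with KCl. On leaving out 1 library, edgeR counts ranged from 74 to 115 with KCl, where 44 were left without KIN10ox libraries 1 and 3, and from 52 to 115 with KNO3. Counts below the 134 and 113 of all libraries came with fewer libraries tested, and the cause of the 115 with KNO3 (without KIN10ox library 3) was not tested. Counts by fold and overlap ranged from 130 to 197 with KCl (197 without KIN10ox library 2) and from 114 to 168 with KNO3 (168 without KIN10ox library 3), since fewer libraries overlap less. No other total moved by more than 1.5 times in the alternatives run, but counts of 1 direction did. With an adjusted p under 0.05 in the authors' tables the falls went from 422 to 272 in KIN10ox, from 139 to 91 with NLP7 and from 62 to 27 with NLP7 and KIN10. Of the 139 NLP7 falls, 107 were at least 2-fold in mean FPKM with all libraries and 92 without GFP library 3. The 12 reversed falls became 27 and 46 with edgeR at an adjusted p under 0.01 and 0.05. The 66 edgeR rises with KIN10 became 17 with a 2-fold minimum, and the 59 falls with KCl became 35 without Ler library 1. By fold and overlap, the 79 rises with KCl became 132 without Ler library 1, the 21 with KNO3 became 36 without Ler library 3 and 33 without KIN10ox library 2, and the 23 with KIN10 over NLP7 became 38 without NLP7 library 3 or NLP7 with KIN10 library 1. Not run, since they need all genes or values not used here, were TMM against median-of-ratios scaling, another pseudocount, an FPKM filter for limma, a probability of at least 0.9, camera and fry. A new test of the authors' own calls is void on genes selected by them. Replicate numbers were not treated as pairs, since in no comparison were all same-numbered pairs correlated over 0.1. Some pairs were, 8 of 18 over the 4 root groups (highest 0.31) and 2 of 3 for nitrate in Ler (highest 0.29). Pairing is thus not excluded. With the replicate number as a block edgeR called 0 differences of the response (192 at an unadjusted p under 0.05), 137 genes with KCl, 116 with KNO3 and 1550 with KIN10 over NLP7, which moved no total by over 1.5 times. No paired analysis was possible of the authors' calls because they come from no test run here; edgeR fits of the same 4 comparisons called 782, 886, 1692 and 640 genes, and 782, 887, 1692 and 606 with the block. Depth limits genes near 0, where folds are lower bounds.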

Other observations

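All tests of explanations in this part were chosen after the results were seen. In mean FPKM, a small set of genes kept most or all of the NLP7-induced rise when KIN10 was added. RBOHD, an NADPH oxidase gene, stood at 48.4 FPKM with GFP, 105 FPKM with NLP7 and 90.3 FPKM with NLP7 and KIN10, so that 73.3% of its rise was left. CYP82C2, a cytochrome P450 gene, kept 107% of its rise, the zinc tolerance gene ZIF1 63.7%, and the jasmonate repressor gene TIFY7 52.8%, against a median of 11.8% over 747 genes. In 10 of the 747 genes more than 50% was left. They are the extremes of the 747, given without a spread or test. Under 50% was left in 733, 739 and 711 genes in NLP7 with KIN10 libraries 1, 2 and 3. All 90 genes with a log2 rise of 3 to 5 and all 162 with a larger rise kept under 50%. RBCS2B kept the most, 179%, but its libraries overlapped between NLP7 and NLP7 with KIN10.

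A few genes moved apart in roots and protoplasts. GolS4, a galactinol synthase gene, fell to 0.442 of its KCl level in Ler roots and rose 189-fold with NLP7, LOG7, a cytokinin activation gene, stood at 0.439 in roots and rose 2.79-fold, and the galactolipid synthase gene MGD2 stood at 0.362 and rose 2.88-fold. Of the 195 genes listed in both, 11 went opposite ways, which left 94.4% with the same direction. Since most genes in both tables rose, a high share comes about without a link.

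Genes that NLP7 raised kept little of that rise when KIN10 was added, although 343 of the 1846 were still listed above GFP. The tables argue against the scaling between libraries as the cause, since a factor moves every gene alike, while the genes that NLP7 lowered changed with KIN10 by a median log2 of 0.46 (interquartile range 0.16 to 0.81) and those that it raised changed by -1.72 (-2.77 to -1.13), ranges that stayed apart without any 1 library. A candidate explanation is that less NLP7 was made. The median share of the rise that was left, 11.8%, lies within the 8.67 to 19.7% of added NLP7 transcript left in the 3 libraries. Per library, the share followed that of the transcript (9.66, 6.59 and 19.1% of the rise at 12.3, 8.67 and 19.7% of the transcript). KIN10 itself had the same order (407, 287 and 546 FPKM), so transfection as a whole may have varied alike, which was not tested. An effect of KIN10 on the NLP7 protein or on its targets stays open beside less NLP7 transcript, since NLP7 protein was not analysed here. Of the 10 splits of these 6 libraries, 1 gave as many edgeR calls, the real one with 1554 and the highest other with 0, and 10 splits are too few for a share under 0.05.

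Photosynthesis genes and others, 285 in all, fell with nitrate in the KIN10ox table and were not in the Ler table. KIN10ox libraries 1 and 3 with KCl may carry these falls: without them 75.1% stayed at least 2-fold lower in mean FPKM, but this rests on the 1 library left. Shoot material in some root samples could give the same pattern. What libraries 1 and 3 held above the KNO3 mean stood in nearly 1 ratio over the photosynthesis genes (interquartile range of its log2 0.60), which a common regulation would give too. A first version, the interquartile range of the KNO3 to KCl log2 ratios, was wide (3.93). It was dropped after its value was seen, its bound being judged wrong, so the later version decides nothing. For the seed genes alone, seed material in library 3 stays open, since 8 of 9 listed seed markers were at least 2-fold higher there than in both other libraries of the group, as does an effect of KIN10.

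The log2 nitrate responses of listed genes were mostly lower in KIN10ox, with a median edgeR difference of -0.26 over 972 genes, which mixes smaller rises with deeper falls. The 136 genes lowered in both genotypes differed by a median of 0.01 in the authors' log2 fold changes (47.8% lower). In mean FPKM, scaled by mapped fragments as edgeR was, they differed by -0.08. The scaling between libraries may account for part of the lower responses. With the authors' scaling the median over the 972 genes was -0.16 (-0.26 to -0.09 on leaving out 1 library), so scaling stays open. The choice of genes by their response in 1 genotype also stays open. Over the 366 genes raised in both, the median was -0.13 with the authors' scaling (-0.17 to -0.05 on leaving out 1 library). In mean FPKM it was -0.22. Values simulated with equal responses gave a median of 0.01 for shared rises. With edgeR they gave 46.8 genes at an unadjusted p under 0.05, 51.5% of them higher in KIN10ox, against 187 observed, 87.2% of them lower. That simulation cannot decide on the choice of genes, since it started from the listed genes and did not repeat the authors' choice among all genes. Splits of the libraries decide nothing for the 0 edgeR calls (41 with DESeq2), since all 100 of 100 splits must reach 0 (highest other 186). Only 4 of 100, the real one included, reached its 187 genes at an unadjusted p under 0.05 (highest other 319), a share under 0.05. Splits that mix the genotypes also carry the differences between them. Genes were listed by their nitrate response within the real genotypes, which can favour the real split, so this share decides nothing either. An effect of KIN10 is likewise open.

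For KIN10ox against Ler, 1 of 10 splits gave as many edgeR calls with KCl (134 in the real split, 31 in the highest other) and 1 of 10 with KNO3 (113 and 0), and 10 splits are too few for a share under 0.05.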
